A study of Macaca mulatta with 4 samples.

How the data were processed

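RNA was sequenced from 4 libraries of rhesus macaque (Macaca mulatta) morulae, the stage at which the embryo is a compacting ball of cells before the blastocyst forms. There were 2 libraries of AG embryos and 2 of GG embryos. The series describes its embryos as androgenetic, with a nuclear genome of paternal origin only, and gynogenetic, with a nuclear genome of maternal origin only. Per the labels' protocols, cDNA was made and amplified with a SMARTer kit for very low RNA input. The labels do not make clear how many embryos went into each library, nor do they say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical. The labels name no molecular identifiers, so reads are not counted as independent molecules, and intervals and floors cover counting error only.

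The deposited table holds estimated counts of reads per Ensembl macaque gene, not scaled to library size, for each library in a column of its own. From 30.0% to 32.2% of the deposited values in a library were not whole numbers. Trim Galore, STAR 2.6.0c and Salmon 0.12.0 and the genome build rheMac8 are named, per the submitters' processing notes, without their role or order; the annotation release, the strand setting and any filter are not given in the sources used here. Estimated counts divide reads among near-identical transcripts, so values of multigene families and of overlapping or antisense genes are uncertain. This holds for SNRPN and SNURF, which share a transcript, and for the RPS4Y, RFPL, ZSCAN5, TPRX and KHDC1 families.

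Symbols were matched by Ensembl gene identifier for 14654 of 21314 genes (68.8%). Where a symbol had several identifiers, the identifier with the most reads was used. XIST, DPPA3, H19, MEG3, PEG3, PEG10, CDX2 and SOX2 had no matched identifier and were not analysed here, nor were the mitochondrially encoded genes, of which 0 of 13 matched. Chromosomes were taken by symbol from a gene table of assembly T2T-MMU8v2.0. That is not the build of the counts, so no coordinates were used.

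Counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with filterByExpr by group (minimum count 10, minimum total 15), TMM normalization and Benjamini-Hochberg adjustment. The model held the group alone. A gene was called at an adjusted p under 0.05. Fold changes are GG minus AG on the log2 scale, and each standard error is the one implied by the F statistic. Levels are in CPM, counts scaled to the TMM-adjusted total of tested genes, given as mean ± SD over 2 libraries. A fold against a group with 0 counts was computed against 3 counts over the group and is a lower bound. With 1 to 3 counts in a group, the ratio of counts over TMM-adjusted totals, each summed over the group, is given with an exact 95% counting interval.

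The groups, the test, 18 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes with the largest change in each direction among called genes with a symbol, a mean of at least 10 CPM and groups that do not overlap. It adds every imprinted gene past the threshold over all genes or over its list alone, up to 4 members with the smallest p from each other list, XIST and DPPA3, and every tested Y-linked gene. Genes named outside it were chosen after their values were seen, and the text says so. The lists hold imprinted genes in 3 classes, markers of epiblast, trophectoderm and primitive endoderm, oocyte and maternal-effect genes, genome activation genes, DNA methylation and Polycomb genes, p53 targets, stress response genes, glycolysis genes, mitochondrially encoded genes, cell cycle genes, Y-linked genes, and markers of cumulus, sperm and blood cells. All matched X-linked genes formed a further list.

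The 18 lists with at least 3 tested members were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted over those lists. None of the camera calls held with a correlation estimated from the data, and that adjusted p is given beside each call. That setting rests on the 2 residual degrees of freedom, whereas the preset correlation does not. A call lost there can therefore reflect low power as well as correlation between genes. The stress response list lost its call at an estimated correlation of -0.0584, below the preset (unadjusted camera p = 0.00693 and 0.101). The other called lists had estimates above the preset. These were 0.0141 for paternally expressed, 0.0549 for trophectoderm, 0.133 for X-linked, 0.272 for Y-linked, 0.409 for genome activation and 0.412 for primitive endoderm genes. For such lists the camera p at the preset can be too small. The median and mean log2 fold changes of the DNA methylation, p53 and glycolysis lists had opposite signs. The difference between X-linked and autosomal medians carries a 95% bootstrap interval over genes from 10000 draws. Genes are not independent replicates. Unlike camera, fry compares a list with no other genes and tests whether its members move one way on balance, so its values are given apart.

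In data simulated for the comparison of GG with AG, over 13227 genes of which 200 were changed, 34% of 4-fold and 93% of 16-fold changes were called, 0 with the wrong sign. Of the called genes, 9.93% were unchanged, and 0 of 20 random lists passed camera. Simulated genes were drawn independently of each other, so the random lists could not test the preset correlation. Far fewer genes were changed there than were called in the data, which makes the adjusted threshold stricter, so these shares need not hold here. Alternatives were other normalizations, other filters on low counts, a robust fit, DESeq2 1.42.0, leaving out each library, the replicate number as a block, and, for lists, fry and an estimated correlation. Thinning each library to the smallest total was added after the data were seen. A check of GC content or gene length was not made, since no annotation of the build was used here.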

Results

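The series concerns genomic imprinting before implantation in a non-human primate, and its design compares the RNA of androgenetic (AG) with that of gynogenetic (GG) macaque morulae. Each group had 2 libraries. Total estimated counts were 14129529 and 19108657 in AG replicates 1 and 2, and 21335844 and 29733897 in GG replicates 1 and 2. Between 15370 and 16313 genes had a count in a library. Across genes, the Spearman correlation was 0.931 between the AG libraries and 0.968 between the GG libraries. It was 0.850 to 0.858 between AG replicate 2 and the GG libraries, and 0.803 to 0.821 between AG replicate 1 and the GG libraries.

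GG and AG morulae differed widely in the genes they expressed. Genes nearly silent in AG and expressed in GG included RRAGD (ENSMMUG00000015262), a GTPase of amino acid sensing, and ACOX2 (ENSMMUG00000006229), a peroxisomal oxidase. With 0 counts in AG, these were at least 408-fold and 361-fold higher in GG, where they reached 36.8 ± 4.04 and 29.5 ± 22.6 CPM (SD, n = 2). S100P (ENSMMUG00000021887), which encodes a calcium-binding protein, rose from 0.158 ± 0.0793 CPM in AG to 185 ± 86.8 CPM in GG (log2 fold change 10.21 ± 0.67 SE, adjusted p = 0.00488). FABP4, a fatty acid-binding protein, and APOE, a lipid carrier, were higher in GG by 9.23 ± 0.77 and 7.76 ± 0.83 on the log2 scale. TMEM176B had 3 counts in AG, and its ratio of GG to AG was 311 (95% interval 106 to 1512). CLDN4, BCL2L14, C9H10orf90 and VWA5A completed the 10 largest increases, with log2 fold changes of 7.48 to 8.58.

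In the other direction, ZNF518B (ENSMMUG00000017761), a zinc finger gene, stood at 64.5 ± 23.0 CPM in AG and had 1 count in GG, a ratio of 3388 (95% interval 607 to 133882). ERMAP, known from red blood cell membranes, was lower in GG by a log2 fold change of -9.16 ± 0.70. The corresponding values were -8.93 ± 0.97 for C4H6orf163, -9.09 ± 1.23 for RFPL1 and -8.81 ± 0.48 for ZSCAN5A; RFPL1 and ZSCAN5A belong to families with near copies and are uncertain. The remaining genes of the 10 largest decreases were RPS4Y1, DDX3Y, SNRPN, LEUTX and ZSCAN4, described with their lists.

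Of 13227 genes tested, 1709 (12.9%) were called with edgeR at an adjusted p under 0.05, 839 higher in GG and 870 higher in AG. In all 1709, both GG libraries lay on the same side of both AG libraries, as did 64.1% of all tested genes against 33.3% by chance. The fitted change was at least 16-fold in 295 genes higher in GG and 269 higher in AG, and the smallest change called was 0.89 on the log2 scale. Without AG replicate 2 the count was 3942, and without GG replicate 1 or GG replicate 2 it fell to 120 and 69, when the spread came from the AG pair alone. Of the 67 named genes called, 45 and 47 then lost their call, and no called gene changed sign in any fit.

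Paternally expressed imprinted genes, which a GG embryo inherits only on maternal chromosomes, were lower in GG as a list. Of 33 on the list, 17 matched and 10 were tested. In GG, 4 were lower, 1 was higher and 5 were not called. SNRPN and SNURF share a transcript but count as 2 of the 4 and as 2 members in the list test. They are not independent evidence for either. SNRPN (ENSMMUG00000023139), a splicing-factor gene of the Prader-Willi region, stood at 165 ± 58.9 CPM in AG and 0.170 ± 0.0956 CPM in GG (SD, n = 2; log2 fold change -9.94 ± 0.61 SE, adjusted p = 0.00488). SNURF, which shares a transcript with SNRPN, had 3 counts in GG, a ratio of AG to GG of 108 (95% interval 36.5 to 528). FAM50B had 1 count in GG, a ratio of 105 (95% interval 18.2 to 4189), and lost its call with the replicate block (adjusted p = 0.0529). USP29, a deubiquitinase gene of the PEG3 domain, stood at 27.4 ± 7.34 CPM in AG and 3.07 ± 0.242 CPM in GG. MEST went the other way, from 34.5 ± 10.02 CPM in AG to 99.4 ± 6.99 CPM in GG (log2 fold change 1.52 ± 0.33 SE, adjusted p = 0.0410). Adjusted over the list alone, 5 were lower in GG, IGF2 being added at 19 counts in AG and 4 in GG. The remaining uncalled members, named after their values were seen, were NDN, INPP5F, ZDBF2 and L3MBTL1. NDN was not silent in GG, with unscaled counts of 83 and 380 in AG replicates 1 and 2 against 272 and 338 in GG. INPP5F had 187 and 86 against 128 and 166, ZDBF2 131 and 159 against 83 and 43, and L3MBTL1 0 and 8 against 12 and 16. The list had a median log2 fold change of -2.23 (camera adjusted p = 0.0157; adjusted p = 0.617 with an estimated correlation, the highest of alternatives that began at 0.0131). The call was also lost without AG replicate 2 (adjusted p = 0.130), without a filter on low counts (0.0622) and with a minimum mean of 10 CPM (0.282).

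Maternally expressed imprinted genes were not called as a list. Of 34, 27 matched and 16 were tested; 2 were higher in GG, 1 was higher in AG and 13 were not called. NLRP2, also known as a maternal-effect gene, stood at 121 ± 58.8 CPM in AG and 869 ± 113 CPM in GG (log2 fold change 2.85 ± 0.40 SE, adjusted p = 0.0190). PHACTR2 was higher in GG by 4.02 ± 0.92 on the log2 scale. SLC22A2, an organic cation transporter, was higher in AG, with 9.33 and 102 CPM in AG replicates 1 and 2 against 0.863 ± 0.257 CPM in GG. Adjusted over the list alone, 4 were higher in GG, KLF14 and PPP1R9A being added, and 1 in AG; both also passed over all genes without AG replicate 2 (adjusted p = 0.0466 and 0.00661) and with DESeq2 (0.0371 and 0.00387). The median log2 fold change was 0.43 (camera adjusted p = 0.177). Of 14 imprinted genes restricted to placenta or linked to histone marks, 8 were tested and 0 were called in either direction, or adjusted over the list alone (edgeR, 0 of 8 at an unadjusted p under 0.05, and 0 called by DESeq2; camera adjusted p = 0.884).

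**Figure D1:**
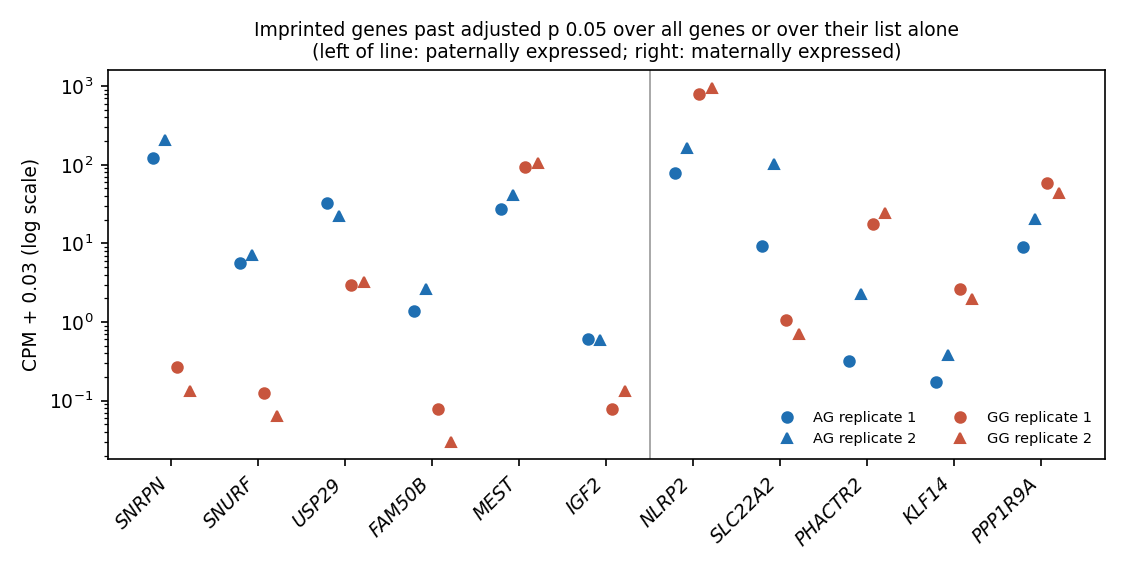
Level of each imprinted gene past the threshold over all genes or over its list alone, in CPM plus a small constant on a log axis; circles are replicate 1, triangles replicate 2, blue is AG and red is GG. SNRPN stood at 123 and 207 CPM in AG and at 0.237 and 0.102 CPM in GG, whereas MEST and NLRP2 were higher in both GG libraries.

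Genes known from the wave of embryonic genome activation were higher in AG. All 10 tested members of the list of 22 had negative log2 fold changes, and 8 were called, 0 of them higher in GG; adjusted over the list alone, 9 were called. ZSCAN4 (ENSMMUG00000005335), a marker of that wave, stood at 1174 ± 213 CPM in AG and 2.28 ± 1.34 CPM in GG (SD, n = 2; log2 fold change -9.02 ± 0.58 SE, adjusted p = 0.00488). CCNA1, a cyclin, was lower in GG by a log2 fold change of -7.95 ± 0.47, ZIM3 by -5.85 ± 0.34 and ZNF280A by -3.24 ± 0.25. LEUTX, a homeobox gene, had 112 CPM in AG replicate 1, 4.42 CPM in AG replicate 2 and 3 counts in GG, a ratio of 830 (95% interval 283 to 4027). Chosen after their values were seen, TPRX1 was lower in GG by -8.44 ± 0.82 and KHDC1L by -1.23 ± 0.26, both uncertain as members of families with near copies. KLF17 is given with the epiblast markers, which also hold it. Over the list, the median log2 fold change was -5.04 (camera adjusted p = 5.6e-06; adjusted p = 0.617 with an estimated correlation, where the other camera alternatives lay between 5.94e-07 and 0.000236). PTPRC, on the blood cell list, was higher in AG too, at 103 ± 53.1 CPM against 4.95 ± 2.13 CPM.

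Markers of trophectoderm, the lineage that forms the placenta, were higher in GG as a list. Of 17 tested, 7 were called, all of them higher in GG. After S100P, the tight junction gene CLDN4 rose from 0.198 ± 0.0788 to 80.7 ± 41.7 CPM, the endocytic receptor gene LRP2 from 0.742 ± 0.243 to 74.3 ± 4.98 CPM, and the epithelial transcription factor gene ELF3 from 7.24 ± 2.18 to 129 ± 32.1 CPM (SD, n = 2; adjusted p = 0.00488 to 0.00871). The other three, GATA2, GCM1 and KRT18, were chosen after their values were seen; GATA2 had 0 counts in AG and was at least 38.2-fold higher in GG. Adjusted over the list alone, 7 were higher in GG and 4 higher in AG, the latter SLC7A2, TFAP2C, DAB2 and AQP3, chosen in the same way. DESeq2 called all 11. Over all genes with edgeR, SLC7A2 (adjusted p = 0.0539) passed without AG replicate 1 or 2 (0.00888 and 0.0464), after thinning (0.0489), with a minimum mean of 10 CPM (0.0403) and without a filter (0.0125). AQP3 passed without AG replicate 2 (0.000795) and without a filter (0.0209), and DAB2 with the replicate block (0.0339) and without a filter (0.0270). GATA3, a central trophectoderm factor also chosen in this way, stood at 1.25 ± 0.253 and 1.18 ± 1.27 CPM in AG and GG and was not called. Over the list, the median was 1.44, also with GATA2 at its bound (camera adjusted p = 0.0479; adjusted p = 0.617 with an estimated correlation, the highest of alternatives that began at 0.0145). Leaving out AG replicate 1, AG replicate 2 or GG replicate 2 ended the call (adjusted p = 0.0635, 0.470 and 0.0876), as did upper-quartile normalization (0.0512), thinning (0.0541) and a minimum mean of 10 CPM (0.140).

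Primitive endoderm markers were also higher in GG as a list, with 4 of 10 tested called higher in GG, 0 higher in AG and 6 not called, over all genes and adjusted over the list alone. Alongside APOE, LAMB1, a laminin chain, rose from 11.2 ± 5.27 to 62.1 ± 8.15 CPM. APOA1 had 1 count in AG, a ratio of 150 (95% interval 26.6 to 5949), and CTSE had 0 counts in AG and was at least 15.6-fold higher in GG. The lineage factors GATA4 and GATA6, chosen after their values were seen, were not called, with log2 fold changes of 0.36 ± 0.54 and 0.09 ± 0.60. Over the list, the median was 1.13, also with CTSE at its bound (camera adjusted p = 0.0316; adjusted p = 0.687 with an estimated correlation, the highest of alternatives that began at 0.0186). Without AG replicate 1 the adjusted p was 0.158, and the calls of APOA1 and CTSE were lost (edgeR adjusted p = 0.0629 and 0.0503), CTSE's also with the replicate block (0.0607). With a minimum mean of 10 CPM the list stood at 0.140.

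Epiblast and pluripotency markers moved both ways. Of 11 tested, 3 were higher in GG, 2 were higher in AG and 6 were not called, also when adjusted over the list alone. TFCP2L1 and ESRRB, transcription factors of naive pluripotency, were higher in GG by 3.79 ± 0.48 and 3.04 ± 0.41 on the log2 scale. DPPA4 and KLF17 were higher in AG, with log2 fold changes of -1.98 ± 0.35 and -4.23 ± 0.76. DPPA2, POU5F1 and NANOG were chosen after their values were seen. DPPA2 was called and stood at 64.5 ± 51.1 CPM in AG and 654 ± 235 CPM in GG. POU5F1 stood at 285 ± 147 and 472 ± 9.69 CPM and NANOG at 87.8 ± 88.7 and 135 ± 8.49 CPM in AG and GG, and neither was called; POU5F1 passed without AG replicate 2 (adjusted p = 0.00794) and NANOG without AG replicate 1 (0.00663), while without AG replicate 2 NANOG was lower in GG and not called (log2 fold change -0.18). For the epiblast list, the median was 0.63 (camera adjusted p = 0.847).

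**Figure D2:**
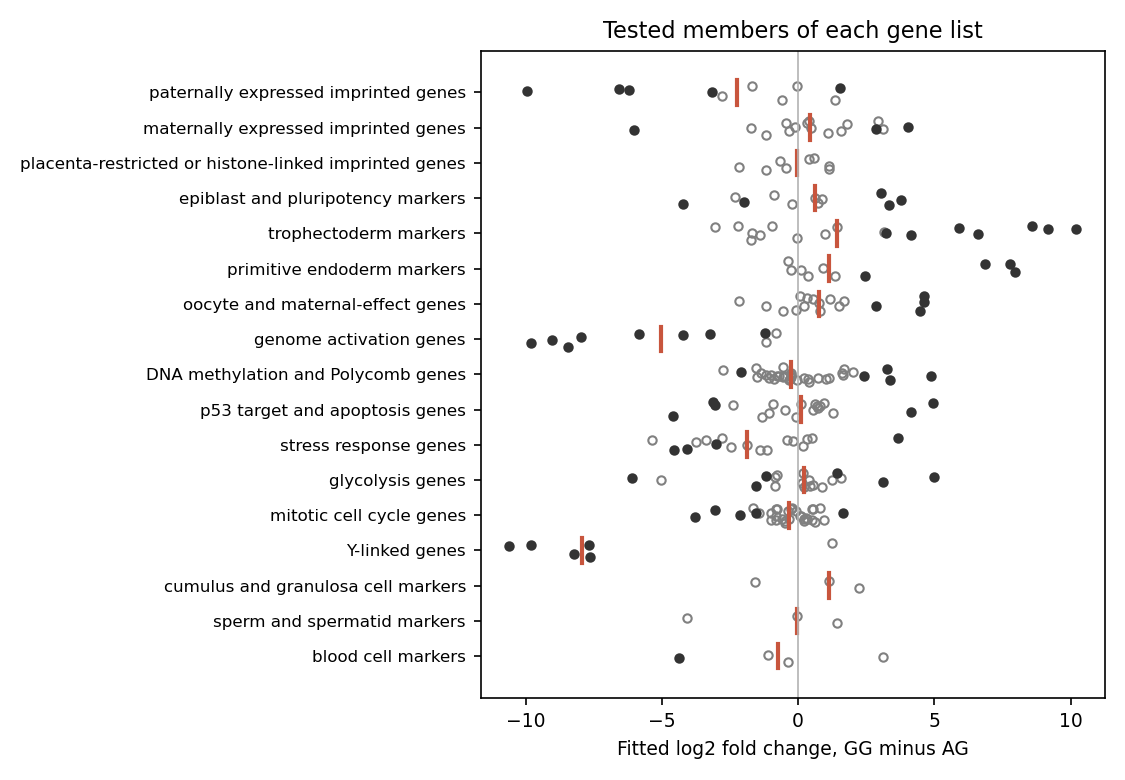
Fitted log2 fold change, GG minus AG, of each tested gene, with a row for each gene list; filled points are genes called over all genes, open points are not called, and red bars are list medians, with vertical scatter only to separate points. All genome activation genes lie left of 0, with a median of -5.04, and the called trophectoderm and primitive endoderm markers lie right of 0.

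Genes of the oocyte and of maternal RNA were not called as a list, although 4 of 17 tested were higher in GG and 0 higher in AG, over all genes and adjusted over the list alone. KHDC3L, of the subcortical maternal complex, stood at 15.4 ± 2.44 CPM in AG and 383 ± 138 CPM in GG (SD, n = 2; log2 fold change 4.63 ± 0.39 SE, adjusted p = 0.00666). GTSF1, a factor of piRNA silencing, was higher in GG by 2.85 ± 0.43, and WEE2, a kinase of the oocyte's meiotic arrest, by 4.47 ± 0.88. KPNA7, an oocyte importin, was higher by 4.61 ± 0.96 and lost its call without AG replicate 1 (adjusted p = 0.0612). Within GG, WEE2 stood at 73.8 and 18.4 CPM and KPNA7 at 43.8 and 8.22 CPM in replicates 1 and 2. Over the oocyte list, the median log2 fold change was 0.78 (camera adjusted p = 0.0544, within alternatives of 0.0107 to 0.618).

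Among DNA methylation and Polycomb genes, 4 of 34 tested were higher in GG, 1 was higher in AG and 29 were not called. The de novo DNA methyltransferase genes DNMT3A and DNMT3B rose from 4.95 ± 0.0439 to 47.4 ± 2.03 CPM and from 1.45 ± 1.25 to 43.6 ± 7.11 CPM (SD, n = 2; adjusted p = 0.0115 and 0.0208). TET2, an enzyme that oxidises methylated cytosine, rose by 2.40 ± 0.40 on the log2 scale. ZFP57, a zinc finger protein that protects methylation at imprinted regions, rose from 3.12 ± 1.69 to 32.3 ± 11.7 CPM. PCGF1, a Polycomb component chosen after its values were seen, was higher in AG by a log2 fold change of -2.10 ± 0.38. The maintenance methyltransferase gene DNMT1, chosen in the same way, stood at 200 ± 126 CPM in AG and 29.4 ± 24.7 CPM in GG and was not called over all genes (adjusted p = 0.0721), but passed without AG replicate 2 (0.0161), with the replicate block (0.0114), without a filter (0.00926) and with DESeq2 (0.000570). Adjusted over the list alone, 5 were higher in GG and 5 higher in AG. The median was -0.27, the mean 0.20, and the list was not called (camera adjusted p = 0.884).

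Stress response genes were higher in AG as a list. Of 17 tested, 3 were higher in AG, 1 was higher in GG and 13 were not called; adjusted over the list alone, 8 were higher in AG and 1 in GG. DDIT3, a transcription factor of the unfolded protein response, stood at 408 ± 117 CPM in AG and 17.3 ± 5.79 CPM in GG (SD, n = 2; log2 fold change -4.56 ± 0.41 SE, adjusted p = 0.00792). ATF3 and PPP1R15A, of the same response, had log2 fold changes of -4.09 ± 0.62 and -3.01 ± 0.64. TXNIP, a thioredoxin inhibitor, was higher in GG, at 107 ± 6.53 CPM against 8.49 ± 2.30 CPM. Stress response genes had a median of -1.89 (camera adjusted p = 0.0249; adjusted p = 0.617 with an estimated correlation, the highest of camera alternatives that began at 0.0118). The call was lost with a minimum mean of 10 CPM (0.0746).

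Of 19 p53 targets and apoptosis genes tested, 2 were higher in GG, 3 were higher in AG and 14 were not called; adjusted over the list alone, 2 and 4 were. SESN2, a stress-induced regulator, PLK3, a kinase, and BCL2L11, a promoter of cell death, were higher in AG, with log2 fold changes of -3.11 ± 0.40, -4.59 ± 0.74 and -3.05 ± 0.68. TP53I3 was higher in GG by 4.14 ± 0.57, as was CASP8, a caspase chosen after its values were seen, by 4.95 ± 1.12; CASP8 lost its call without AG replicate 1 or 2 (adjusted p = 0.0543 and 0.0624) and with the replicate block (0.0642). The list was not called, with a median of 0.11, a mean of -0.11 and a negative direction in camera (adjusted p = 0.884).

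Glycolysis genes moved both ways, with 3 of 19 tested higher in GG, 3 higher in AG and 13 not called. The phosphofructokinase genes PFKP and PFKL rose in GG, PFKP from 6.55 ± 1.22 to 209 ± 3.32 CPM (SD, n = 2; 31.9-fold, adjusted p = 0.00488) and PFKL by 3.10 ± 0.49 on the log2 scale. The lactate dehydrogenase genes differed in direction. LDHB (ENSMMUG00000002679) was higher in GG, at 6303 ± 1541 CPM against 2337 ± 136 CPM. LDHA, chosen after its values were seen, was higher in AG, at 5327 ± 727 CPM against 1818 ± 543 CPM. ENO2, an enolase, had a log2 fold change of -6.11 ± 1.05, and the lactate transporter SLC16A1, chosen in the same way as LDHA, -1.18 ± 0.28; the call of SLC16A1 (adjusted p = 0.0482) ended with DESeq2 size factors (0.0501) and upper-quartile normalization (0.0538). Adjusted over the list alone, 3 were higher in GG and 6 in AG. The median was 0.23, the mean -0.06 (camera adjusted p = 0.884).

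Of 33 mitotic cell cycle genes tested, 1 was higher in GG, 4 were higher in AG and 28 were not called; adjusted over the list alone, 1 and 6 were. RRM1, the large subunit of ribonucleotide reductase, stood at 3117 ± 562 CPM in AG and 224 ± 13.98 CPM in GG (SD, n = 2; log2 fold change -3.80 ± 0.25 SE, adjusted p = 0.00488). CDC6, which loads replication origins, CCNE2, a cyclin of S phase entry, and PCNA, the replication clamp, had log2 fold changes of -2.14 ± 0.27, -3.03 ± 0.52 and -1.54 ± 0.29. TTK, a spindle checkpoint kinase chosen after its values were seen, was higher in GG by 1.65 ± 0.37. The list was not called, with a median of -0.33 (camera adjusted p = 0.117).

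Y-linked RNA was found in both AG libraries and was near 0 in GG. Of 6 Y-linked genes tested, 5 were higher in AG, over all genes and adjusted over the list alone. Their summed level was 179 CPM in AG replicate 1 and 1526 CPM in AG replicate 2, 8.54 times as much, against 1.99 and 1.43 CPM in GG. This ratio covers called genes only. Of the 11 matched, ZFY, KDM5D, NLGN4Y, SRY and TBL1Y were not tested and are named after their values were seen. They had 0, 2, 0, 0 and 0 counts in AG replicate 1, and 143, 116, 9, 3 and 0 in AG replicate 2. In GG, KDM5D had 6 and 1 counts, NLGN4Y 8 and 7, and the others 0. DDX3Y and RPS4Y1 had log2 fold changes of -9.79 ± 1.35 and -10.61 ± 1.58, EIF1AY -7.67 ± 1.43 and RPS4Y2 -8.21 ± 1.22; RPS4Y1 and RPS4Y2 are near copies and are uncertain. USP9Y had 2 counts in GG, a ratio of 256 (95% interval 70.4 to 2124), and lost its call without AG replicate 2 (adjusted p = 0.0537). UTY was not called, at 1.83 ± 0.139 CPM in AG and 4.28 ± 0.0733 CPM in GG, and was kept in the list median and test. A GG embryo has no paternal genome and so no Y chromosome. Reads given to UTY in GG therefore cannot be RNA of the embryo's own Y chromosome. The value of UTY is uncertain because it has a close X-linked relative, KDM6A. That limit holds for any Y-linked gene here with a close X-linked relative, not for UTY alone. Y-linked genes had a median of -7.94 (camera adjusted p = 0.0157; adjusted p = 0.617 with an estimated correlation, the highest of alternatives that began at 0.00232).

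X-linked genes were higher in GG than in AG relative to autosomal genes. Of 390 tested, 59 were higher in GG, 12 were higher in AG and 319 were not called; adjusted over the list alone, 70 and 15 were. The median log2 fold change of X-linked genes lay above that of 10147 autosomal genes by 0.59 (95% bootstrap interval over genes 0.42 to 0.79). Against AG replicate 1 the GG libraries were higher by 0.29 and 0.39, and against AG replicate 2 by 0.95 and 0.96. X-linked genes were lower in AG replicate 2 than in AG replicate 1 by a difference of -0.65 (-0.73 to -0.52), and the GG libraries differed by -0.01 (-0.07 to 0.05). The list was called (camera adjusted p = 0.000112; adjusted p = 0.687 with an estimated correlation, the highest of alternatives that began at 4.81e-09). Without AG replicate 2 the call was lost (adjusted p = 0.130).

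**Figure D3:**
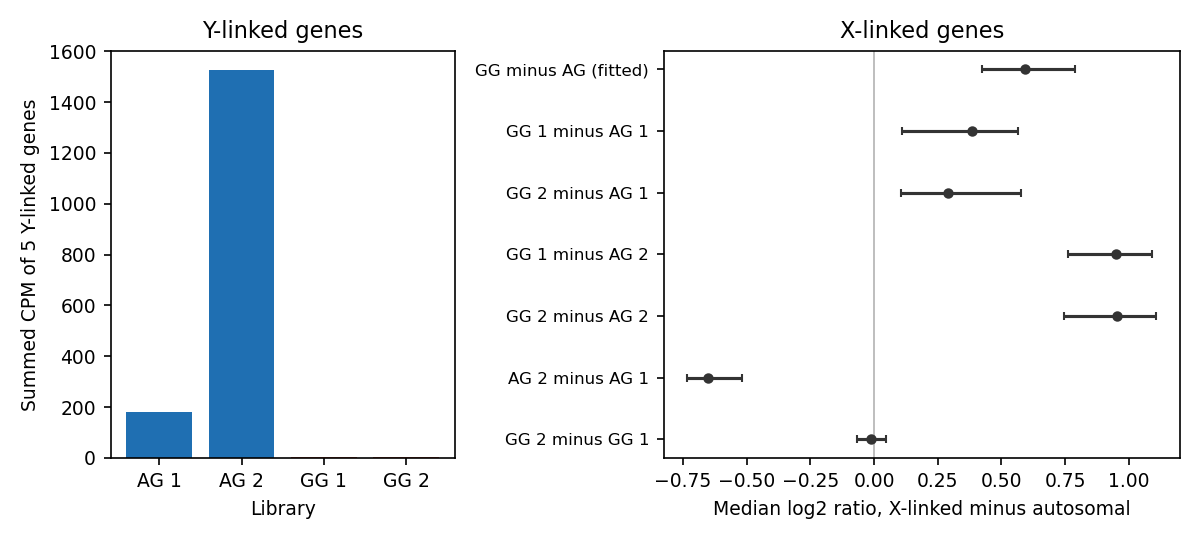
Left, summed CPM of the 5 called Y-linked genes in each library, with AG in blue and GG in red; right, median log2 ratio of X-linked minus autosomal genes for each contrast, with 95% bootstrap intervals over genes. The bars reach 179 and 1526 CPM in AG and stay below 2 CPM in GG, and all 5 contrasts of GG with AG lie above 0.

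Markers of other cell types that embryo collection can carry over were few among tested genes. Of cumulus and granulosa cell markers, 3 were tested and 0 were called (edgeR, 1 at an unadjusted p under 0.05, and 1 called by DESeq2). VIM stood at 35.9 ± 12.05 CPM in AG and 12.1 ± 3.96 CPM in GG and was higher in AG adjusted over the list alone. Over all genes, VIM passed with the replicate block (edgeR adjusted p = 0.0479), without a filter on low counts (0.0359) and with DESeq2 (0.00881). Without AG replicate 1 its log2 fold change was -1.88. TNFAIP6 and CYP11A1 had overlapping groups, although CYP11A1 passed without AG replicate 2 (0.0301), and the list was not called (camera adjusted p = 0.953). Of sperm markers, 3 were tested and 0 were called, also adjusted over the list alone (edgeR, 1 at an unadjusted p under 0.05, and 1 called by DESeq2; camera adjusted p = 0.847). IZUMO1 stood at 2.83 ± 1.84 CPM in AG and 0.153 ± 0.217 CPM in GG and passed without AG replicate 2 (adjusted p = 0.0472), while SPACA1 and ODF2 had overlapping groups. Of 4 blood cell markers tested, PTPRC was higher in AG (log2 fold change -4.39 ± 0.57 SE, adjusted p = 0.0168). LYZ stood at 0.849 ± 0.596 CPM in AG and 7.59 ± 3.15 CPM in GG and passed adjusted over the list alone. Over all genes, LYZ passed with the replicate block (edgeR adjusted p = 0.0399) and without a filter on low counts (0.0175). It also passed with DESeq2 (adjusted p = 0.00125), which called 2 of the 4 markers. Without AG replicate 2 its log2 fold change was 4.12. The haemoglobin gene HBA1 and the platelet gene PPBP stayed at 1.97 ± 2.15 and 0.869 ± 0.423 CPM in AG, with overlapping groups, and the list was not called (camera adjusted p = 0.847).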

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

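Thinning was chosen after the data were seen; the other alternatives were not. Counts of calls stayed within 1.5 times the main count in 22 comparisons and left that range in the others given here. No called gene changed sign. The 1709 calls became 2609 without a filter on low counts (1360 higher in AG), where 18261 genes were tested, and 3339 with DESeq2 (1628 higher in GG, 1711 higher in AG), which called 1708 of the 1709; the cause was not tested. Leaving out a library gave 69 to 3942 calls, 41 to 2096 higher in GG and 28 to 1846 higher in AG. The low values came without a GG library, when the spread rested on the AG pair and the lone GG library was assumed to vary like it; 115 and 68 of the 1709 were called then. Other normalizations, the robust fit, thinning and a minimum of 10 CPM gave 1454 to 1783. With the replicate block, 1697 genes were called, 1430 of them shared; same-numbered replicates deviated together by a correlation across genes of only 0.0986, which gives little sign that the numbers pair the samples. The block ended the calls of FAM50B, CTSE, CASP8 and ATP5IF1 (adjusted p = 0.0529, 0.0607, 0.0642 and 0.0512) and called DNMT1, DAB2, VIM and LYZ (0.0114, 0.0339, 0.0479 and 0.0399), and USP9Y lost its call in the robust fit and after thinning (adjusted p = 0.0564 after thinning).

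The paternally expressed list (adjusted p = 0.0157) went to 0.617 with an estimated correlation, 0.0622 without a filter, 0.282 with a minimum of 10 CPM, which tests fewer members, and 0.0131 to 0.130 over the fits without a library. With an estimated correlation, all 7 called lists lost their call, at 0.617 to 0.687. That setting rests on 2 residual degrees of freedom, so low power could end these calls. Correlation between genes could end them too. Its estimate was 0.133 to 0.412 for the X-linked, Y-linked, genome activation and primitive endoderm lists, against the preset 0.01. The oocyte list passed without a filter (0.0107), with a minimum of 10 CPM (0.0195), after thinning (0.0384) and with the block (0.0491). By fry, which asks whether members move one way and not how they compare with other genes, adjusted p was 5.72e-05 for stress response, 0.0306 for the paternally expressed, genome activation, trophectoderm and mitotic lists, 0.128 for Y-linked genes and 0.139 for primitive endoderm and X-linked genes. Lists that changed direction were not called in any fit that reversed them. These were DNA methylation (0.330 with fry, 0.721 with a minimum of 10 CPM) and cumulus (0.975 with fry, 0.805 without a filter). Over the fits that left out a library, direction changed in DNA methylation (adjusted p 0.750 to 0.998), cumulus (0.787 to 0.998), glycolysis (0.497 to 0.914), placenta-linked imprinted genes (0.749 to 0.998), epiblast (0.674 to 0.954) and p53 targets (0.749 to 0.914). Of the genes the rule names, uncalled ones that changed sign in those fits were ODF2 (log2 fold change -0.14 to 0.0059), HBA1 (-2.08 to 0.99) and PPBP (-1.04 to 0.23); the cause was not tested. Among 30 genes named outside the rule, GATA3 changed sign without AG replicate 1 and without GG replicate 1 (0.17 and 0.74), GATA4 without GG replicate 1 (-0.20), GATA6 without AG replicate 1 and without GG replicate 2 (-0.48 and -0.13) and NANOG without AG replicate 2 (-0.18), all uncalled then; these 30 kept direction and side of the threshold in 284 comparisons, lost the call in 46 and gained it in 19. Over the other results, genes the rule names kept direction and side of the threshold in 820 comparisons, lost the call in 100 and gained it in 18. With 2 libraries a group, 34% of simulated 4-fold changes were called. The simulation changed 200 of 13227 genes, while 1709 were called in the data. The adjusted threshold was therefore stricter in the simulation, and 34% is not the sensitivity here. Uncalled genes can still differ by 4-fold.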

Other observations

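In all, 15 gene families were chosen after the data were seen, and so were the tests of remaining oocyte RNA, of thinned trophectoderm markers, of GG RNA in AG replicate 2 and of sex-linked dosage within AG. Families were formed by symbol, so they can hold assembly factors and other genes that share a symbol prefix. Zinc finger genes were lower in GG as a family, with 41 of 336 tested higher in AG, 4 higher in GG and a median log2 fold change of -0.67 (camera adjusted p = 2e-06 over 15 families; adjusted p = 0.617 with an estimated correlation). ZNF791 stood at 92.2 ± 11.6 CPM in AG and 0.409 ± 0.242 CPM in GG, and ZNF679 at 163 ± 71.4 and 1.28 ± 0.803 CPM (SD, n = 2). The family holds genes of the genome activation list, among them ZSCAN4 and ZNF280A, so the lists are not independent. Genes of respiratory complex I and its assembly factors were higher in GG, 6 of 28 called with 0 higher in AG. Their median was 0.77 (camera adjusted p = 0.0019, or 0.617 with an estimated correlation). The called genes included the assembly factor NDUFAF7. NDUFB5 stood at 62.2 ± 31.5 and 284 ± 8.89 CPM in AG and GG. Of complexes III to V, 3 of 20 were higher in GG and 1 was higher in AG, the latter ATP5IF1, an inhibitor of ATP synthase (median 0.79, adjusted p = 0.0108; adjusted p = 0.617 with an estimated correlation). The call of ATP5IF1 (adjusted p = 0.0482) ended with DESeq2 size factors (0.0526), upper-quartile normalization (0.0504), the robust fit (0.0504) and the replicate block (0.0512). Mitochondrial ribosomal protein genes had 5 of 45 higher in GG but were not called (adjusted p = 0.0619), and 0 of 62 cytosolic ribosomal protein genes were called by edgeR (5 at an unadjusted p under 0.05, and 2 called by DESeq2).

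Proton pump genes of the V-ATPase were higher in GG in 5 of 18 cases and higher in AG in 1, ATP6V1E1 (median 0.63, adjusted p = 0.0413; adjusted p = 0.617 with an estimated correlation). ATP6V1B1 stood at 0.285 ± 0.403 and 36.0 ± 12.3 CPM in AG and GG. Of 7 claudins, 3 were higher in GG and CLDN12 was higher in AG, at 136 ± 14.7 against 32.2 ± 10.8 CPM; the family was not called (adjusted p = 0.440). Antiviral restriction factors had 3 of 9 higher in GG, 0 higher in AG and 6 not called, and the family was called (camera adjusted p = 0.0073; adjusted p = 0.617 with an estimated correlation). It was picked from genes seen to differ and is no independent evidence. The other families, also chosen after the data were seen, are no independent evidence either. Its members TRIM22 and TRIM5 were higher in GG by 4.35 ± 0.56 and 4.17 ± 0.57 on the log2 scale, while of 36 tripartite motif genes, which include both, 4 were higher in GG, 2 were higher in AG and 30 were not called (camera adjusted p = 0.535). The families of solute carriers, proteasome-related genes, keratins, RAB proteins, apolipoproteins and histones were not called (camera adjusted p 0.105 to 0.866).

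X-linked genes were higher in GG relative to autosomal genes. After thinning to equal totals, the difference was 0.56 (95% interval 0.41 to 0.77). Thinning keeps each gene's expected share of the counts, and the values were already scaled to library size. It could hardly have moved the difference, so it does not decide whether deeper sequencing of GG plays a part. A candidate explanation is a single X chromosome in part of the AG embryos, since an AG embryo takes its sex chromosomes from sperm. The AG library with 8.54 times the Y-linked RNA had X-linked genes lower than the other AG library by a difference of -0.65 (-0.73 to -0.52), as that hypothesis needs. GG replicates 1 and 2 still lay above AG replicate 1, the AG library with less Y-linked RNA, by 0.39 (0.11 to 0.56) and 0.29 (0.11 to 0.58). Whether a single X chromosome covers that remainder was not tested. The hypothesis rests on 2 AG libraries, and how X dosage is set in each group was not tested.

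Genome activation genes were high in AG and trophectoderm markers high in GG. The genome activation median was -5.09 after thinning. The log2 fold changes of trophectoderm markers moved on thinning by a median of only -0.12 (95% bootstrap interval -0.16 to -0.01). Thinning keeps expected shares of counts, so it could hardly have moved these medians and does not decide whether depth plays a part. The trophectoderm median was 1.44 (-1.40 to 5.89) before and 1.37 (-1.53 to 5.71) after thinning, the 7 called markers stayed called, and SLC7A2, higher in AG, was called in addition (adjusted p = 0.0489). As a list they went from an adjusted p of 0.0479, close to the threshold, to 0.0541. An earlier stage of AG embryos with more remaining oocyte RNA stays open. The oocyte and maternal-effect list had a median of 0.78 toward GG (0.08 to 1.68), against that explanation, but it was not called (camera adjusted p = 0.0544) and its genes are not independent. A difference in developmental pace, or in parental genome as the design names it, may account for the pattern too, and the design does not separate these from the group.

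Within AG, replicate 2 lay nearer to GG than replicate 1 in 65.4% of the called genes, whereas GG replicate 2 was displaced away from AG in 56.8%. Of all tested genes, 1325 differed at least 4-fold between the AG libraries and 515 between the GG libraries. The 65.4% became 66.2% after thinning, which keeps expected shares of counts and so does not decide whether depth plays a part. As the whole of the pattern, GG RNA mixed into AG replicate 2 is argued against. Such a mix needs the same share from all genes. Called genes higher in AG needed a median of 19.4% GG RNA, and those higher in GG 1.11% (95% bootstrap interval 0.55 to 1.60). The difference was 18.3 percentage points (95% bootstrap interval 14.7 to 23.0). A small share of GG RNA, beside other differences between the AG libraries, is not excluded. Called genes held only 71 X-linked and 5 Y-linked genes. Leaving out so few could not move the share much, so it does not test different dosage of sex-linked genes. The pattern was not confined to them, since 65.4% (62.7 to 68.0%) of 1267 called autosomal genes were displaced toward GG. Of 71 called X-linked genes 60.6% were displaced that way too, although all 390 tested X-linked genes together were lower in AG replicate 2 (-0.65), away from GG. Differences between AG embryos in stage, or effects of sex chromosomes on autosomal genes, remain possible and were not tested, and the labels name no factor that separates the AG libraries.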
